A study of Gallus gallus with 21 samples.

How the data were processed

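Retina was taken from control White Leghorn chickens, and each of the 21 libraries was made from total RNA after depletion of ribosomal RNA, with a protocol that keeps the strand. Per the labels, the birds belonged to 3 groups of 7, at 1, 3 and 6 days after a start at postnatal day 3, so that their ages at collection were 4, 6 and 9 days after hatching. The group of each library came from its title, and each library has a code of its own with a final letter L or R. The labels state neither the sex of the birds nor whether any bird gave more than 1 library, so the tests measure the spread between libraries. No paired analysis was possible because no title number occurs in more than 1 group. The letter L ended 3, 3 and 5 of the codes at 1, 3 and 6 days.

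The authors deposited 1 table of CPM values, the reads of a gene scaled to a fixed library total, with 18631 genes and 1 column per library. Its lowest value in every column was 0.0001, an offset that was subtracted here. Per the labels, STAR, Partek and the genome build GRCg6a were used. Their versions, the annotation, the use of the strand in counting and the handling of reads that fall in several genes are not stated. Low values lay on whole multiples of 1 step per library, from 0.0241 to 0.0361 CPM, for 94.3% to 95.5% of the values within a tolerance of 0.1 of a step. With each step taken as 1 read, they give a total of 27.7 to 41.4 megareads per library. The genes given hold 29.9% to 34.2% of that total, or 8.65 to 13.8 megareads, so most of each total lies outside the table. Whole reads were not recovered for every value, and no test on counts was run. Fold changes on the log2 scale with a pseudocount understate changes of genes near the pseudocount.

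Positions are those the table gives on GRCg6a. A RefSeq gene table of another build, with 15419 of the 18631 symbols, served for chromosome names alone. Of the 143 genes named by the rule below, 13 overlapped another gene of the table on the same strand, 33 overlapped one on the other strand, and 6 lay on chromosome Z. Histone genes and other near copies share sequence, and how their reads were assigned is not known.

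Genes were kept at 0.5 CPM or more in at least 7 libraries, which left 12614. Values were analysed as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, with 1 mean per group, a mean-variance trend in the empirical Bayes step, and Benjamini-Hochberg adjustment within each comparison. An adjusted p under 0.05 counted as past the threshold, and "rose" and "fell" are used of such genes. The 3 pairs of groups were compared, and 2 further tests asked whether a gene differed at any time and whether its change from 3 to 6 days differed from that from 1 to 3 days. All limma p-values are two-sided. Gene lists for 37 pathways, cell types and complexes were fixed, of which 34 had at least 5 genes tested. Of the list genes, 30 belong to more than 1 list. Each list was compared with the other genes by camera in limma, with a preset correlation of 0.01 between genes and adjustment over 34 lists, and again with the correlation estimated from the data.

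The genes named are, in each comparison, the 8 largest rises and the 8 largest falls past the threshold with a gene symbol and a higher group mean of at least 5 CPM, and from each list up to 4 genes with the smallest adjusted p from 1 to 6 days, or the most abundant gene where none passed. The groups, the filter, the pseudocount, the tests, the gene lists, this rule and the first set of alternatives were chosen before the data were examined. Other genes are named with the statement that they were chosen after their values were seen. An exact two-sided permutation test of each list's mean relative to its library's median, over all 3432 ways to divide 14 libraries, was added after the results were seen, as was the same test without subtraction of that median. The smallest possible p of either is 0.000583.

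The workflow was tested on simulated data with 50 changed genes per size between 1 and 6 days and 12515 genes tested. It recovered 42.0% of 1.25-fold rises, 82.0% of 1.5-fold rises, 90.0% of 2-fold rises and 72.0% of 0.667-fold falls. It called 10 of 12315 unchanged genes, and 0 of 12515 in the comparison of 3 with 1 day, which held no simulated change. Changed genes were drawn from those with a mean of at least 1 CPM. Genes were simulated independently of each other, without W-linked differences between libraries and without shifts of whole libraries. The rates therefore do not cover these features of the real data.

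Alternatives fixed at the start were other pseudocounts of 0.05 and 2.5, no filter, a floor of 2.5 CPM, median-of-ratios scaling, quantile normalization, the 2 groups alone, array weights, robust empirical Bayes, the title letter as a covariate, leaving out each library in turn, and the estimated correlation for lists. Added after the data were seen were the mean log2 level of 35 W-chromosome genes as a covariate, alone and with median-of-ratios scaling, the genes outside chromosomes Z and W alone, the 13 libraries with W-linked transcripts alone, log2 of the total reads as a covariate, and scaling to the sum of the values given. For each model result, 100 divisions of the libraries into groups of the same sizes, the true one included, were fitted with a fixed seed. The lens-treated birds of the wider study and its other tissues were not analysed here. Some genes are not reported here by name, and they stay in all counts and list tests.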

Results

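Transcripts were measured in the retina of untreated chickens at 3 ages in the first days after hatching, with 7 libraries each at 1, 3 and 6 days (postnatal day 4, 6 and 9). These birds are the controls of a study of how the eye answers a lens that shifts the image out of focus, and the comparisons ask how retinal transcripts change with age without a lens. Total reads, estimated from the steps between low values, were 35.1 ± 3.82 megareads at 1 day, 37.4 ± 3.06 megareads at 3 days and 35.6 ± 2.31 megareads at 6 days (SD, n = 7 each). The genes given took 30.99 ± 0.688%, 31.8 ± 0.912% and 33.4 ± 0.454% of those totals. Pairwise correlations between libraries across genes lay between 0.969 and 0.991. Below, gene levels are mean CPM ± SD with n = 7 per group, changes are log2 fold changes from limma, and "x of 7 libraries" counts the libraries of the later group that lay on that side of the earlier group's mean. The largest rises and falls are ranked among genes with a symbol and a higher group mean of at least 5 CPM.

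HINTW, a gene of the W chromosome that female birds alone carry, divided the libraries. It stood at 121 to 147 CPM in 13 libraries and at 0.0286 to 0.549 CPM in 8. Those with W-linked transcripts were 3 of 7 at 1 day, 4 of 7 at 3 days and 6 of 7 at 6 days. Genes of the Z chromosome, of which males carry a pair, moved with this division. The median Z gene minus the median autosomal gene was -0.29 to -0.13 in the 13 libraries and 0.25 to 0.34 in the other 8 (log2 deviations from the mean of all 21).

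**Figure D1:**
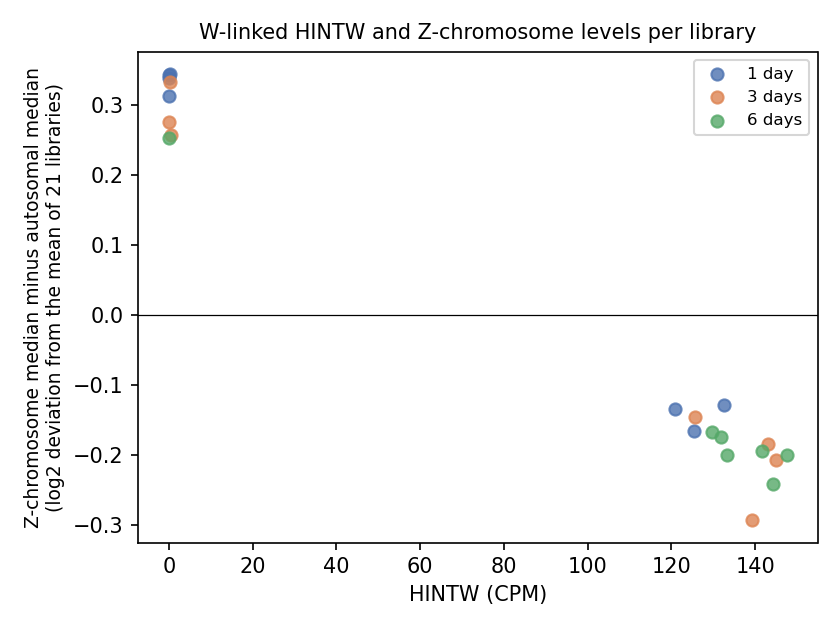
Level of the W-linked gene HINTW (CPM, horizontal axis) and median deviation of Z-chromosome genes minus that of autosomal genes (log2, vertical axis), 1 point per library, coloured by time point. The 13 libraries with HINTW at 121 CPM or more all lie below 0, and the 8 others all lie above it.

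From 1 to 6 days, 13 of 21 rod genes and 8 of 17 cone genes of light detection rose, beside 3779 of all 12614 genes tested. The cone list did not pass with camera (adjusted p = 0.555). The cone opsin gene OPN1LW, for long wavelengths, went from 70.8 ± 26.8 CPM at 1 day to 133 ± 26.5 CPM (+1.00, SE 0.25, adjusted p = 0.00398). OPN1MSW, for medium wavelengths, went from 32.1 ± 8.45 to 60.9 ± 9.54 CPM (+0.95, SE 0.16, adjusted p = 0.000199). The largest rise belonged to NR1D1_1 (chromosome 28, 2283345 to 2295938), whose symbol is that of a nuclear receptor of the circadian clock, at 3.41 ± 1.29 and 9.73 ± 2.88 CPM (+1.41, SE 0.23, adjusted p = 0.000186). The largest fall was that of ANGPTL7 (chromosome 21, 4171755 to 4180470), a secreted angiopoietin-like protein, from 5.02 ± 4.17 to 1.06 ± 0.71 CPM (-1.66, SE 0.33, adjusted p = 0.000895, 7 of 7 libraries). At 1 day, 1 library, C10R, held 13.9 CPM of it. In the libraries with W-linked transcripts alone, 3 of 7 at 1 day and 6 of 7 at 6 days, the opsin rises were smaller, at +0.46 for OPN1LW, no longer past the threshold (adjusted p = 0.0749), and +0.57 for OPN1MSW (adjusted p = 0.0150). NR1D1_1 stood there at +0.88 (adjusted p = 0.0141), below ISCA2 at +0.94.

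In all, 4103 of 12614 genes passed the threshold, with 3779 rises and 324 falls. The median gene lay at +0.14, and 3731 of the 4103 lay above it and 372 below. With median-of-ratios scaling, which sets the median gene near 0, there were 1041 rises and 1124 falls, and with quantile normalization 1032 and 993. At least a doubling was seen in 6 genes and at least a halving in 10. Noncoding RNA made up 34.9% of the falls, 2.04% of the rises and 7.85% of the genes tested. RN7SL1, the RNA of the signal recognition particle, took 4.29 ± 0.358% of the summed values at 1 day and 3.48 ± 0.306% at 6 days.

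Other large rises were those of ISCA2, which assembles iron-sulfur clusters in mitochondria (3.84 ± 0.686 to 8.84 ± 1.05 CPM, +1.11, SE 0.13, adjusted p = 1.68e-05), and SOUL, a heme-binding protein (+0.86). ARL2BP, a partner of the small GTPase ARL2 (+0.91), AN1ZNF5L, a zinc finger protein (+0.85), and FN1, fibronectin (+0.95, adjusted p = 0.0392), rose too. Besides ANGPTL7, large falls were those of EGR1, a transcription factor that neurons induce within minutes of activity (11.6 ± 4.46 to 6.36 ± 2.14 CPM, -0.80, SE 0.29, adjusted p = 0.0394), TMC1, a channel protein of hair cells (-0.70), and the histone gene HIST1H2BO (-0.68). Next came DFNB59, needed for hearing (-0.61), PRKG2, a kinase driven by cyclic GMP (-0.59), RAPSN, which clusters acetylcholine receptors (-0.56), and CNTNAP4, a neuronal adhesion protein (-0.52). TMC1 and CNTNAP4 lie on chromosome Z and changed by -0.35 and -0.25 with the W-linked covariate, both still past the threshold. EGR1, FN1 and HIST1H2BO no longer passed with that covariate (adjusted p = 0.119, 0.132 and 0.108), nor did FN1 with median-of-ratios scaling (adjusted p = 0.102). In the libraries with W-linked transcripts alone AN1ZNF5L stood at +0.47, FN1 at +0.42 and TMC1 at -0.29, none past the threshold.

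Among rod phototransduction genes, 13 of 21 rose and 0 fell (14 and 0 adjusted over the list alone), among them the rod exchanger SLC24A1 (+0.81), the cyclase activator GUCA1B (+0.56) and GNB1, a transducin subunit (+0.50). The list lay above other genes with camera (adjusted p = 0.00362), a call lost with an estimated correlation (adjusted p = 0.689 with an estimated correlation). Relative to the library median its mean was 0.19 higher at 6 days (exact permutation test, adjusted p = 0.0481, 7 of 7 libraries). Of the cone genes, 8 of 17 rose and 0 fell (8 and 1 adjusted over the list alone), including the short-wavelength opsin OPN1SW (+0.99) and PDE6H (+0.26), a phosphodiesterase subunit, with adjusted p = 0.555 for the list. Glycolysis enzymes showed 13 rises and 0 falls in 21 genes (14 and 0 adjusted over the list alone), with hexokinase HK1 at +0.46, PGK1 at +0.44, enolase ENO2 at +0.46 and aldolase ALDOC at +0.54. The camera call for glycolysis (adjusted p = 0.00444) was lost at adjusted p = 0.661 with an estimated correlation. Of the ribosomal protein genes, 39 of 72 rose and 0 fell (41 and 0 adjusted over the list alone), with RPLP0 at +0.51, RPL4 at +0.37 and RPL13 at +0.40. Their camera call (adjusted p = 0.00362) was likewise lost (adjusted p = 0.707 with an estimated correlation). In the exact permutation test relative to the library median, glycolysis (+0.10, adjusted p = 0.105) and ribosomal protein genes (+0.04, adjusted p = 0.440) did not pass.

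With median-of-ratios scaling the rod, glycolysis and ribosomal lists had 6, 7 and 10 rises and 1, 1 and 2 falls. Cholesterol synthesis had 12 rises and 0 falls in 22 genes (16 and 0 adjusted over the list alone), with SREBF2, the regulator of sterol synthesis, at +0.64 and the enzymes FDFT1 at +0.59 and CYP51A1 at +0.57. With median-of-ratios scaling it had 4 rises and 0 falls. As a list it did not pass (adjusted p = 0.0525).

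The lower lists were histones and immediate early genes. Of the histone genes, 7 of 33 fell and 1 rose (7 and 1 adjusted over the list alone, 10 and 1 with median-of-ratios scaling). The linker histone genes HIST1H103, HIST1H110 and HIST1H111R stood at -0.47, -0.56 and -0.38, and H2AFY2, a macroH2A variant of nondividing cells, at +0.40. The camera call (adjusted p = 1.47e-05) was lost with adjusted p = 0.587 with an estimated correlation. Among immediate early genes, 3 of 17 rose and 3 fell (3 and 3 adjusted over the list alone, 1 and 4 with median-of-ratios scaling). EGR1, the orphan receptor NR4A3 (-0.40) and the phosphatase DUSP6 (-0.29) fell, while KLF6 (+0.38) and JUN (+0.30) were among the rises. The list was lower with camera (adjusted p = 0.00773), but not with an estimated correlation (adjusted p = 0.436 with an estimated correlation), quantile normalization (adjusted p = 0.125), median-of-ratios scaling (adjusted p = 0.191) or the W-linked covariate (adjusted p = 0.0669). Relative to the library median its mean was lower by exact permutation (-0.24, adjusted p = 0.00991, 7 of 7 libraries). Lower by the same exact permutation test were also histones (-0.28, adjusted p = 0.0481, 6 of 7 libraries), eye growth signals (-0.16, adjusted p = 0.00991), thyroid hormone genes (-0.17, adjusted p = 0.0132), clock genes (-0.11, adjusted p = 0.0446) and amacrine genes (-0.06, adjusted p = 0.0481). Without subtraction of the library median none of these 6 lists passed as lower in that test. Amacrine genes (+0.11, adjusted p = 0.00220) and clock genes (+0.07, adjusted p = 0.00743) were then higher. Eye growth signals (+0.02), thyroid hormone genes (0.00), immediate early genes (-0.07) and histones (-0.11) did not pass (adjusted p from 0.266 to 0.942).

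The eye growth list, of signals tied to the control of eye size, had 6 rises and 5 falls in 32 genes (6 and 5 adjusted over the list alone, 2 and 7 with median-of-ratios scaling, camera adjusted p = 0.0525). Its members BMP7, a growth factor (+0.55), the adenosine receptor ADORA2B (+0.54) and the dopamine receptor DRD1 (+0.18) rose, and BDNF, a neurotrophin, fell from 4.96 ± 0.838 to 3.53 ± 0.825 CPM (-0.46). Thyroid hormone genes had 3 rises and 2 falls in 11 (3 and 3 adjusted over the list alone, 1 and 3 with median-of-ratios scaling), with the corepressor NCOR1 at +0.41, the transporter SLCO1C1 at +0.40 and the target KLF9, on chromosome Z, at -0.31. Their median was -0.13 and their mean 0.00. Heat shock and protein folding had 8 rises and 0 falls in 21 (10 and 0 adjusted over the list alone, 2 and 1 with median-of-ratios scaling), with the chaperones HSPA5 at +0.53, HSP90B1 at +0.39 and the cochaperone BAG3 at +0.76. Clock and melatonin genes had 10 rises and 5 falls in 26 (10 and 5 adjusted over the list alone, 4 and 6 with median-of-ratios scaling), with ARNTL at +0.76, CLOCK at +0.32, CRY1 at +0.31 and HLF at +0.25.

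Lists of neurons, matrix and metabolism had more rises than falls, and with median-of-ratios scaling the balance of several turned. Synapse genes had 13 rises and 2 falls in 40 (14 and 2 adjusted over the list alone, 2 and 9 with median-of-ratios scaling), with the release regulators CPLX3 at +0.58 and RIMS2 at +0.24. Ion channels had 11 and 0 in 29 (14 and 1 adjusted over the list alone, 5 and 7 with that scaling), with KCNA2 at +0.44 and SCN8A at +0.36. Axon guidance had 12 and 0 in 29 (12 and 0 adjusted over the list alone, 2 and 3 with that scaling), with the receptor PLXNA2 at +0.46. Neurogenesis had 8 and 1 in 22 (8 and 2 adjusted over the list alone, 3 and 5 with that scaling), with the transcription factor NEUROD4 at +0.84 and nestin, NES, at +0.57. Nuclear oxidative phosphorylation genes had 10 and 0 in 68 (4 and 0 adjusted over the list alone, 1 and 2 with that scaling), with NDUFS3 at +0.42. Extracellular matrix had 9 and 1 in 28 (10 and 1 adjusted over the list alone, 1 and 2 with that scaling), with the laminin LAMC1 at +0.62. Hypoxia response had 7 and 1 in 19 (8 and 1 adjusted over the list alone, 1 and 1 with that scaling), with the hexokinase HK2 at +0.62. No list of this paragraph passed with camera, which compares a list with the other genes.

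Among markers of retinal cell classes, rises numbered 6 of 22 for amacrine cells (6 adjusted over the list alone), 6 of 16 for ganglion cells (9 adjusted over the list alone) and 4 of 10 for horizontal cells (4 adjusted over the list alone). They numbered 3 of 14 for bipolar cells (3 adjusted over the list alone) and 2 of 16 for Muller glia (1 adjusted over the list alone). Falls numbered 0 in each of these lists, also adjusted over the list alone. With median-of-ratios scaling their rises and falls were 1 and 4, 1 and 2, 0 and 1, 2 and 1, and 0 and 1. Examples were CHAT, the acetylcholine enzyme of starburst amacrine cells (+0.43), and ONECUT1 of horizontal cells (+0.45). Visual cycle genes had 3 rises and 0 falls in 15 (3 and 0 adjusted over the list alone), and retinoic acid genes 2 and 0 in 12 (2 and 0 adjusted over the list alone). Proliferation genes had 3 and 0 in 21 (1 and 0 adjusted over the list alone) and interferon response 3 and 0 in 18 (3 and 0 adjusted over the list alone). HELZ2 of the interferon list stood at +0.70. With median-of-ratios scaling these 4 lists had 1 and 1, 0 and 1, 0 and 0, and 1 and 0.

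Markers of tissues that could enter a retina sample gave few calls. Calls numbered 1 rise in 10 pigment epithelium genes (0 adjusted over the list alone). RPE65, the isomerase of the visual cycle, was that gene, at 2.24 ± 0.661 and 3.61 ± 0.799 CPM. There were 0 calls in 6 lens genes, 1 rise in 7 crystallins, 1 rise in 9 fibroblast genes and 0 calls in 5 endothelial genes. Leukocyte genes had 1 rise in 11 and muscle genes 1 in 4, too few for a list test. These 6 lists had the same counts adjusted over the list alone. CRYBA4, the most abundant lens gene, stood at 16.5 ± 1.65 and 16.9 ± 1.26 CPM, and KDR of the endothelial list at 36.0 ± 5.85 and 38.4 ± 5.29 CPM. Whether cells of the retina itself express genes of the lists in this paragraph was not tested. Oligodendrocyte genes had 2 rises and 1 fall in 11 (2 and 1 adjusted over the list alone, 1 and 2 with median-of-ratios scaling), with GPR17, a receptor of their precursors, at +0.60 and the myelin protein PMP2 at -0.87. Of 20 erythroid genes 4 were in the table and 0 passed the filter, and 0 of 28 mitochondrially encoded genes were in it.

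Of 34 lists tested from 1 to 6 days, 5 passed with the preset correlation, 3 up and 2 down, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). In the exact permutation test relative to the library median, 7 passed, 1 higher and 6 lower. In the 13 libraries with W-linked transcripts alone, 862 genes passed, 776 up and 86 down. ARNTL (+0.43) and GPR17 (+0.28) did not pass there.

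At 3 days, compared with 1 day, 12 of 21 heat shock and folding genes fell and clock genes moved both ways. HSPA8, a constitutive chaperone (chromosome 24, 3102900 to 3107843), went from 497 ± 58.5 to 292 ± 59.6 CPM (-0.78, SE 0.11, adjusted p = 7.75e-05, 7 of 7 libraries). HSP90AA1, a stress chaperone (chromosome 5, 49679064 to 49684242), went from 557 ± 89.4 to 319 ± 81.4 CPM (-0.83, SE 0.14, adjusted p = 0.000672, 7 of 7 libraries). ARNTL, the clock activator also called BMAL1 (chromosome 5, 7819805 to 7864577), rose from 16.3 ± 3.95 to 38.1 ± 5.30 CPM (+1.22, SE 0.14, adjusted p = 7.80e-06, 7 of 7 libraries). NDRG1, a stress-responsive gene (chromosome 2, 141967427 to 142007619), rose from 70.6 ± 10.7 to 143 ± 18.5 CPM (+1.01, SE 0.09, adjusted p = 5.34e-07, 7 of 7 libraries). PDK4, which holds back pyruvate dehydrogenase, rose from 20.7 ± 4.18 to 42.6 ± 8.76 CPM (+1.02, SE 0.13, adjusted p = 3.54e-05).

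**Figure D2:**
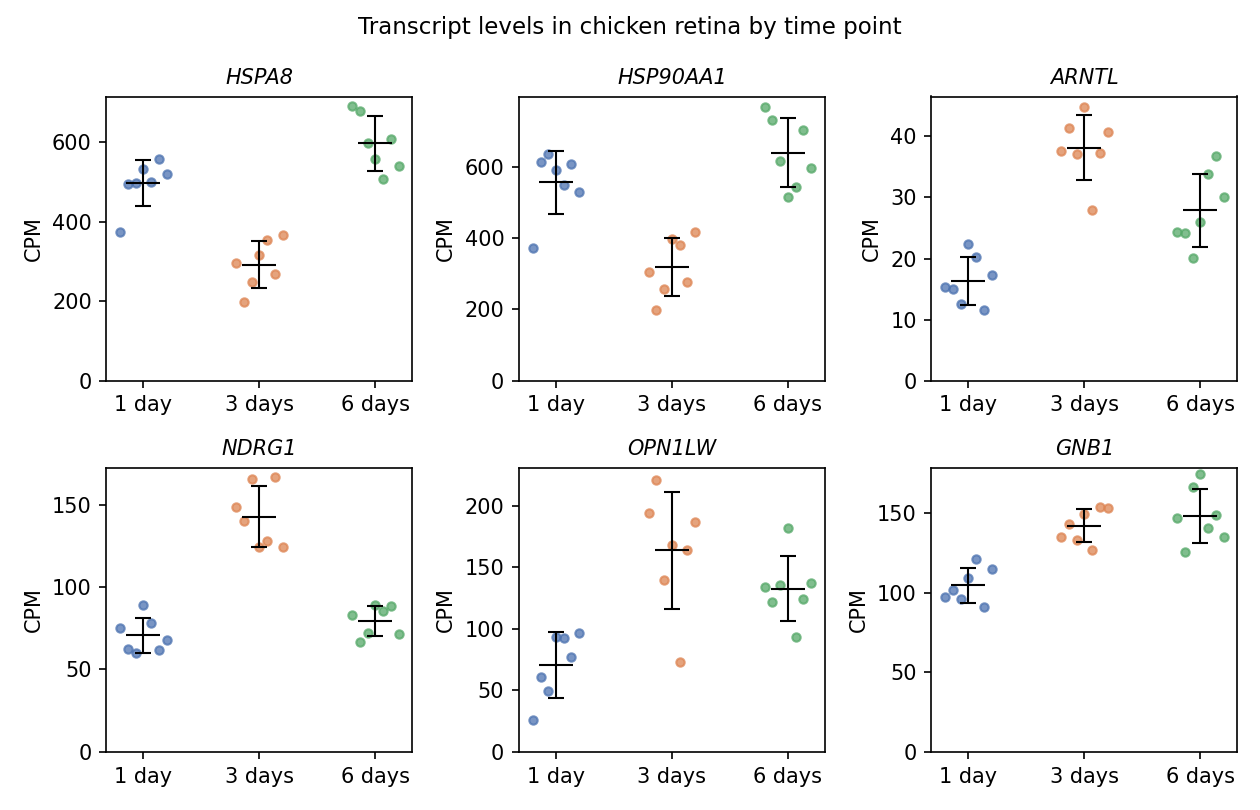
Levels of HSPA8, HSP90AA1, ARNTL, NDRG1, OPN1LW and GNB1 (CPM, vertical axes from 0) at 1, 3 and 6 days, 1 point per library, with the mean and SD of 7 libraries in black. HSPA8 and HSP90AA1 are lowest at 3 days, with means of 292 and 319 CPM, ARNTL and NDRG1 are highest then, with means of 38.1 and 143 CPM, and GNB1 has its highest mean, 148 CPM, at 6 days.

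The threshold was passed by 1279 of 12614 genes, 972 up and 307 down, with the median gene at +0.07. The rises and falls numbered 570 and 695 with median-of-ratios scaling, and 573 and 608 with quantile normalization. At least a doubling was seen in 12 genes and at least a halving in 3. The other largest rises were NR1D1_1 (+1.25), the opsin gene OPN1LW (70.8 ± 26.8 to 164 ± 47.5 CPM, +1.25, SE 0.25, adjusted p = 0.00212), the kinase NEK10 (+1.02), SOUL (+0.99) and UBAP1L (+0.97). NEK10 did not pass in the libraries with W-linked transcripts alone (+0.65). Under the rule for named genes, the other largest falls were RSRP1, an arginine- and serine-rich protein (135 ± 42.3 to 59.5 ± 19.2 CPM, -1.14, SE 0.20, adjusted p = 0.000688), and the chaperones HSPH1 (-0.92) and DNAJA1 (-0.82). They were joined by the RING finger protein LONRF1 (-0.90), EHD4, of endosome recycling (-0.86), and RBP4, the carrier of retinol in blood (221 ± 32.9 to 131 ± 30.5 CPM, -0.77). DNAJA1 and RBP4 lie on chromosome Z, and libraries with W-linked transcripts numbered 3 of 7 at 1 day and 4 of 7 at 3 days.

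In the heat shock and protein folding list, 12 of 21 genes fell and 0 rose (13 and 1 adjusted over the list alone). With camera the list was lower (adjusted p = 7.35e-16), with adjusted p = 0.110 with an estimated correlation. Its mean relative to the library median was 0.46 log2 units lower (exact permutation test, adjusted p = 0.0396, 7 of 7 libraries). Cholesterol synthesis had 8 rises and 0 falls in 22 (12 and 0 adjusted over the list alone), with FDFT1 at +0.55, SREBF2 at +0.49 and CYP51A1 at +0.47. Its camera call (adjusted p = 0.00137) was lost at adjusted p = 0.871 with an estimated correlation. Glycolysis had 5 rises and 0 falls in 21 (9 and 0 adjusted over the list alone), with ENO2 at +0.36 and HK1 at +0.22. Its camera call (adjusted p = 0.0344) was lost with an estimated correlation (adjusted p = 0.871 with an estimated correlation) and with median-of-ratios scaling (adjusted p = 0.0921).

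Cone phototransduction had 3 rises and 3 falls in 17 (6 and 8 adjusted over the list alone), with OPN1LW and OPN1MSW (+0.97) rising. Its median was -0.14, its mean +0.03 and its camera direction down (adjusted p = 0.0344). That call was lost with an estimated correlation (adjusted p = 0.871 with an estimated correlation), quantile normalization (adjusted p = 0.309), median-of-ratios scaling (adjusted p = 0.188) and the W-linked covariate (adjusted p = 0.0703). The rod list had 6 rises and 3 falls in 21 (8 and 6 adjusted over the list alone), with SLC24A1 at +0.77, GNB1 at +0.44 and PDE6B, the rod phosphodiesterase on chromosome Z, at -0.67. Clock and melatonin genes had 6 rises and 4 falls in 26 (8 and 7 adjusted over the list alone). Chosen after their values were seen, the activators NPAS2 and ARNTL2 stood at +0.60 and +0.50, and the repressors PER2, PER3 and CRY2 at -0.66, -0.67 and -0.35. ABCA4, which clears retinal from photoreceptor discs, rose from 156 ± 9.70 to 226 ± 16.2 CPM (+0.53, SE 0.05, adjusted p = 7.94e-07).

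Of the 34 lists, 4 passed from 1 to 3 days, 2 up and 2 down, and 0 with an estimated correlation (1 at an unadjusted p under 0.05). In the exact permutation test relative to the library median, 1 passed, heat shock and protein folding. Cholesterol synthesis (adjusted p = 0.159), glycolysis (adjusted p = 0.159) and cone phototransduction (adjusted p = 0.578) did not pass in that test. Counts leaned on single libraries of both groups. There were 2150 genes without C42L and 841 without C33R, both of 3 days, and 862 without C18R, of 1 day. The lists passing numbered 2 without C18R, C23R or C34L in turn, and 2 with median-of-ratios scaling.

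From 3 to 6 days, 15 of 21 heat shock and folding genes and 8 of 21 rod genes rose. HSPA8 reached 597 ± 68.6 CPM (+1.05, SE 0.11, adjusted p = 3.51e-06, 7 of 7 libraries) and HSP90AA1 641 ± 96.7 CPM (+1.03, SE 0.14, adjusted p = 3.36e-05, 7 of 7 libraries). RSRP1 reached 173 ± 11.9 CPM (+1.58, SE 0.20, adjusted p = 1.51e-05, 7 of 7 libraries). PDE6B (chromosome Z, 53573478 to 53602211) went from 45.7 ± 9.58 to 91.6 ± 10.8 CPM (+1.02, SE 0.13, adjusted p = 1.51e-05). RDH8, the photoreceptor enzyme that reduces retinal (chromosome 8, 14341966 to 14351136), went from 42.5 ± 10.1 to 91.3 ± 18.99 CPM (+1.10, SE 0.17, adjusted p = 0.000115). NDRG1 fell from 143 ± 18.5 to 79.5 ± 9.25 CPM (-0.84, SE 0.09, adjusted p = 5.74e-06), and PDK4 from 42.6 ± 8.76 to 21.9 ± 3.70 CPM (-0.94, SE 0.13, adjusted p = 5.25e-05).

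The threshold was passed by 2813 of 12614 genes, 2191 up and 622 down, with the median gene at +0.07. The rises and falls numbered 1088 and 1074 with median-of-ratios scaling, and 1103 and 1113 with quantile normalization. At least a doubling was seen in 12 genes and at least a halving in 29. Noncoding RNA made up 27.8% of the falls. The other largest rises were STS, steroid sulfatase (+1.66, SE 0.59, adjusted p = 0.0458), RAD54L2, a helicase (+1.22), and the chaperone HSPA2 (+1.07). STS ranged from 2.22 to 73.5 CPM within the 3-day group and no longer passed with the W-linked covariate (adjusted p = 0.0846), with median-of-ratios scaling (adjusted p = 0.0675) or in the libraries with W-linked transcripts alone (+0.36, adjusted p = 0.464). Under the rule for named genes, the largest falls were NEBL1 (150 ± 58.2 to 42.4 ± 30.8 CPM, -1.96, SE 0.51, adjusted p = 0.00778), CD69L, a C-type lectin (-1.60, adjusted p = 0.0472, and 0.0594 with the W-linked covariate), and NEK10 (-1.24). Those of UBAP1L (-1.10), BMPER, which binds bone morphogenetic proteins (-1.03), CCDC169 (-0.94) and RAPSN (-0.87) followed. CD69L ranged from 4.52 to 22.1 CPM at 3 days and from 0.335 to 18.4 CPM at 6 days, so the groups overlapped. NEBL1 overlapped too, at 44.8 to 213 CPM at 3 days and 14.4 to 102 CPM at 6 days. Within the 1-day group NEBL1 ranged from 16.1 to 207 CPM.

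In the heat shock list, 15 of 21 genes rose and 0 fell (15 and 0 adjusted over the list alone), including the folding factors BAG3 (+0.95), AHSA1 (+0.73), HSPA5 (+0.68) and HSP90B1 (+0.59). The list was higher with camera (adjusted p = 1.53e-09) but not with an estimated correlation (adjusted p = 0.574 with an estimated correlation). Its mean relative to the library median rose by 0.50 (exact permutation test, adjusted p = 0.0198, 7 of 7 libraries). Rod genes had 8 rises and 0 falls in 21 (9 and 0 adjusted over the list alone), with camera adjusted p = 0.00866 and adjusted p = 0.723 with an estimated correlation. Cone genes had 10 rises and 0 falls in 17 (10 and 0 adjusted over the list alone), OPN1SW at +0.58 among them, with camera adjusted p = 0.0109 and adjusted p = 0.592 with an estimated correlation. Relative to the library median, the rod mean was 0.21 and the cone mean 0.16 higher (exact permutation tests, adjusted p = 0.0264 for each, 7 of 7 libraries for each).

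Histone genes had 8 falls and 1 rise in 33 (8 and 2 adjusted over the list alone, 10 and 0 with median-of-ratios scaling), with HIST1H2BO at -0.75, HIST1H103 at -0.55 and HIST1H110 at -0.49. Their camera call (adjusted p = 7.82e-06) was lost at adjusted p = 0.592 with an estimated correlation. Histones did not pass in the exact permutation test relative to the library median either (-0.33, adjusted p = 0.0753). The interferon list had 4 falls and 1 rise in 18 (4 and 1 adjusted over the list alone), and 0 rises with median-of-ratios scaling. IFIT5, chosen after its values were seen, fell from 1.48 ± 0.540 to 0.449 ± 0.274 CPM (-1.07). The list was lower with camera (adjusted p = 0.0342), which was lost with an estimated correlation (adjusted p = 0.642 with an estimated correlation), quantile normalization (adjusted p = 0.428), median-of-ratios scaling (adjusted p = 0.189) and the W-linked covariate (adjusted p = 0.0773). Its mean relative to the library median was lower in the exact permutation test (-0.25, adjusted p = 0.0264, 7 of 7 libraries). The same exact permutation test gave lower means for eye growth signals (-0.14, adjusted p = 0.0198), proliferation (-0.07, adjusted p = 0.0264) and clock genes (-0.08, adjusted p = 0.0425). Without subtraction of the library median none of these 4 lists passed, with the interferon list at -0.15 (adjusted p = 0.215), eye growth at -0.04 (adjusted p = 0.215), proliferation at +0.02 (adjusted p = 0.450) and clock genes at +0.02 (adjusted p = 0.524). Clock genes had 6 rises and 5 falls in 26 (7 and 5 adjusted over the list alone), with ARNTL at -0.46, CLOCK at +0.23, CRY1 at +0.27 and HLF at +0.24. Of the 34 lists, 5 passed with camera, 3 up and 2 down, and 0 with an estimated correlation (2 at an unadjusted p under 0.05). In the exact permutation test relative to the library median, 7 passed, 3 higher and 4 lower. In the libraries with W-linked transcripts alone, 4 of 7 at 3 days and 6 of 7 at 6 days, 1202 genes passed, and HIST1H2BO did not (-0.36).

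**Figure D3:**
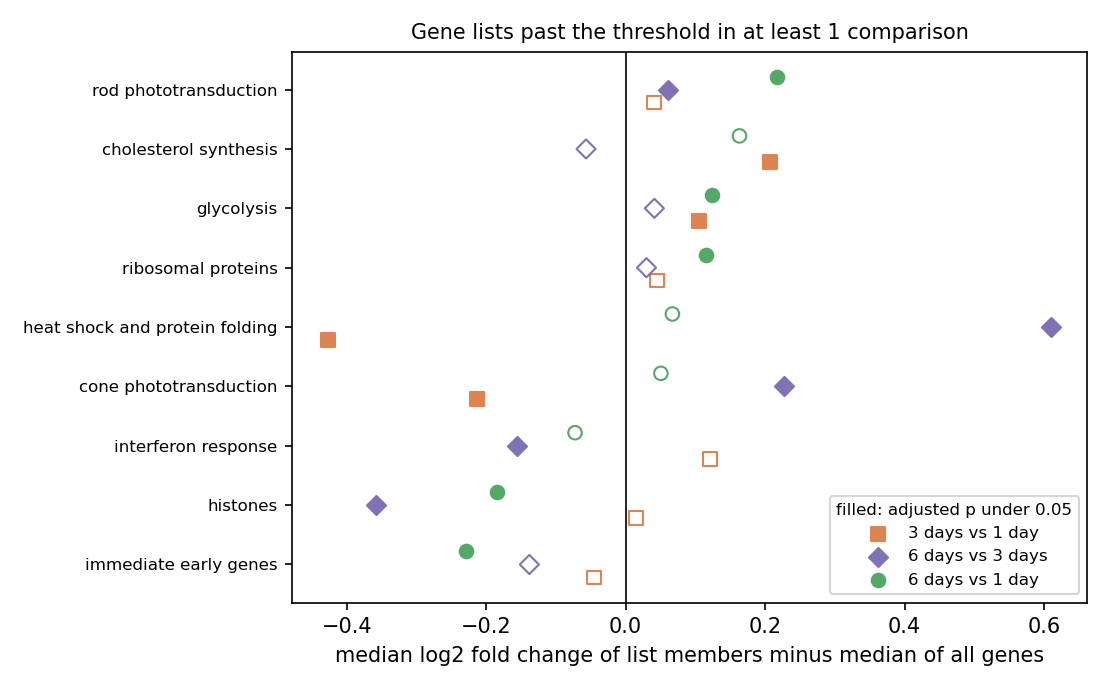
Median log2 fold change of the genes of each list minus the median of all genes (horizontal axis) for the lists past the threshold in at least 1 comparison. There is 1 marker shape and colour per comparison, and markers are filled where camera with the preset correlation gave an adjusted p under 0.05. Heat shock and protein folding lies at -0.43 from 1 to 3 days and at +0.61 from 3 to 6 days, and no filled marker passed with an estimated correlation.

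Across the course, 4865 of 12614 genes differed at some time, and for 1489 the change from 3 to 6 days differed from that from 1 to 3 days, upward for 798 and downward for 691. The steps differ in length, so total changes and not rates were compared. HSPA8 (difference +1.83, adjusted p = 1.59e-06), LONRF1 (+1.88, adjusted p = 1.59e-06) and EHD4 (+1.73, adjusted p = 1.59e-06) turned upward. NDRG1 (-1.85, adjusted p = 2.02e-07), NEK10 (-2.25, adjusted p = 9.75e-06) and ABCA4 (-0.81, adjusted p = 2.79e-06) turned downward. Genes that fell from 1 to 3 days and then rose numbered 228, and genes that rose and then fell 231. The 3-day libraries enter both steps, which by itself yields opposite changes. When each step used different 3-day libraries, 3 for 1 step and 4 for the other, the 35 divisions gave a median of 75 and 67 genes and a lowest count of 25 and 39. Steps that call genes independently would give a median of 12.002 and 9.04 in these divisions. Genes with a small spread pass more easily in both steps, so the excess does not measure reversal alone. Both parts of the 3-day group also share whatever was common to its collection.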

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

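Of the tests below, the W-linked covariate for the heat shock genes and for the share of rises, the median-of-ratios scaling for the heat shock genes, and the clock genes as a set were chosen after the results were seen.

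In 24 of 429 combinations of named gene and group (5.59%), 1 library stood apart from the other 6 by more than Dixon's limit, and chance gives about 1 in 20. The value given is its gap to the nearest library as a share of the group's range, both on log2(CPM + 0.5). C10R, at 1 day, was lowest for AHSA1 (11.98 CPM against 16.3 in the nearest library, 0.766), HSPA8 (375 against 496 CPM, 0.701), HSP90AA1 (374 against 529 CPM, 0.652) and GRIK1 (130.1 against 148 CPM, 0.665). It was highest for RAPSN (13.8 against 9.13 CPM, 0.580). C42L, at 3 days, was lowest for ARNTL (27.9 against 37.2 CPM, 0.602), NR1D1_1 (3.76 against 7.25 CPM, 0.582), OPN1LW (73.0 against 139.7 CPM, 0.586) and ALDOC (201 against 281 CPM, 0.580).

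Among the other libraries at 3 days, C34L was lowest for NEBL1 (44.8 against 125 CPM, 0.657) and FN1 (1.21 against 4.05 CPM, 0.705). C33R was highest for NEUROD4 (5.57 against 2.44 CPM, 0.573) and SOX9 (1.26 against 0.531 CPM, 0.608). C44R was highest for AHSA1 (15.4 against 12.5 CPM, 0.611) and lowest for PDE6H (562 against 638 CPM, 0.596), and C31L was lowest for CRYL1 (2.23 against 2.63 CPM, 0.621). At 1 day, C22L was highest for BNIP3L (309 against 286 CPM, 0.595), C17L was highest for EOMES (1.15 against 0.744 CPM, 0.642) and C18R was lowest for CRY1 (33.3 against 36.8 CPM, 0.675). At 6 days, C65L was lowest for BDNF (1.95 against 3.26 CPM, 0.589) and highest for the Z-linked KLF9 (83.5 against 66.2 CPM, 0.638). C64L was highest for CLOCK (122 against 111 CPM, 0.588), C62L for ENO2 (380 against 347 CPM, 0.650) and C57L for NDUFB9 (14.7 against 12.9 CPM, 0.645).

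Heat shock genes were lower at 3 days than at 1 and 6 days, with 12 falls and then 15 rises among 21. With the W-linked covariate 12 still fell from 1 to 3 days, and with median-of-ratios scaling 13. Neither adjustment could change this step much. Libraries with W-linked transcripts numbered 3 of 7 and 4 of 7, and the median gene lay at +0.07. Differences this small argue against the W-linked shares and the scaling as the whole cause of a mean change of -0.39 in the list. A candidate explanation is another phase of the daily clock at collection, whose time the labels do not give. The mean of 5 activator-side clock genes minus that of 10 repressor-side ones changed by +0.88 from 1 to 3 days (two-sided exact permutation p = 0.000583, the smallest possible). It changed by -0.45 from 3 to 6 days (exact p = 0.00291). The names of the sides are labels, since the activator side also holds NFIL3, a repressor, and the repressor side HLF, which is not a repressor. NR1D1_1 did not enter the set, because the repressor side lists this gene by the symbol NR1D1. It rose together with ARNTL from 1 to 3 days, which runs against the shift of the set. Because the set was chosen after its values were seen, these p-values describe the shift and do not test the explanation. Within groups the link to heat shock level could not be told from none over 21 libraries (Pearson r = -0.34, permutation p = 0.142, adjusted 0.142, and Spearman rho = -0.47, permutation p = 0.0423, adjusted 0.0847, with r = -0.35 without the 2 libraries farthest from the median). Age itself stays open, since each group has 1 age and the time of day of its collection is not known.

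Rises far outnumbered falls from 1 to 6 days, at 92.1% of 4103 calls. The share was 92.2% with log2 of the total reads as a covariate and 91.2% with the W-linked covariate. The 91.2% argues against the W-linked shares as the whole cause. Total reads were alike at 1 and 6 days (35.1 ± 3.82 and 35.6 ± 2.31 megareads), so the depth covariate could hardly move the share. These like totals, and not that covariate, argue against depth as the whole cause. The median gene stood at +0.138 in the main fit, +0.139 with the depth covariate and +0.112 with the W-linked covariate. Rises numbered 3779 in the main fit, 3722 with the depth covariate and 2698 with the W-linked covariate. The share of rises cannot show such a partial effect, so a contribution of the W-linked shares is not excluded. Reads outside the genes given took a smaller share at 6 days (the genes given held 30.99% of the total at 1 day and 33.4% at 6 days), and scaling to the sum of the values given lowered the share of rises to 68.2%. The 68.2% lies between the 60% set before this scaling was run for that cause and the 80% set against it, so it decides neither way. This part cannot be told apart from a change with age in any case. The share held by the genes given did not overlap between 1 day (at most 31.9%) and 6 days (at least 32.9%). A change of many retinal genes with age was not tested apart from this.

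Genes of chromosome Z lay below autosomal genes from 1 to 6 days, by -0.26 at the median, with 22 rises and 43 falls among 611. Different shares of birds with W-linked transcripts may account for this: with the W-linked covariate the gap was -0.044, and there were 86 rises and 19 falls. In the 13 libraries with W-linked transcripts alone it was also -0.04. No biological explanation beyond the sex chromosomes was tested.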

How the results depend on the processing

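The W-linked covariate, the genes outside chromosomes Z and W, the libraries with W-linked transcripts alone, the depth covariate, the scaling to the sum of the values, every alternative for lists from 1 to 3 and from 3 to 6 days, median-of-ratios scaling for lists from 1 to 6 days, and every alternative but quantile normalization for the difference between the steps were chosen after the data were seen. The count tests of edgeR and DESeq2 were not run, because whole reads were not recovered for every value. From 1 to 6 days, 4103 genes became 2165 with median-of-ratios scaling, 2025 with quantile normalization, 2366 with scaling to the sum of the values, and 1361 with the W-linked covariate and median-of-ratios scaling together. Median-of-ratios scaling shifts the median gene from +0.14 to 0.00, and beyond that the cause was not tested. In the 13 libraries with W-linked transcripts alone, with fewer libraries, the counts were 862, 270 and 1202 for 1 to 6, 1 to 3 and 3 to 6 days, 1647 at any time and 567 for the difference between the steps. The count at any time was 2962 with the W-linked covariate and median-of-ratios scaling together. All other alternatives that kept all libraries left the gene counts within 1.5 times. Similar counts can hold different genes. From 1 to 3 days, 877 of the 1265 genes with median-of-ratios scaling were among the 1279 of the main fit. With quantile normalization 873 of 1181 were. With an estimated correlation, 0 lists passed in each comparison, and with median-of-ratios scaling 2 lists passed from 1 to 3 days. Leaving out 1 library in turn gave 3398 to 4284 genes from 1 to 6 days, 841 (without C33R) to 2150 (without C42L) from 1 to 3 days (these 2 beyond 1.5 times), 2204 to 3207 from 3 to 6 days, 4230 to 5254 at any time and 1032 to 1798 for the difference between the steps. Lists passing ranged from 5 to 7, from 2 (without C18R, C23R or C34L) to 5, and from 4 to 5. Of 240 calls for named genes, 0 reversed under the alternatives that tested them, which covered 218 with the floor of 2.5 CPM, 228 outside chromosomes Z and W, 239 with the 2 groups alone and all 240 otherwise. Calls lost numbered 68 with median-of-ratios scaling, 69 with quantile normalization, 50 with scaling to the sum of the values, 22 with the W-linked covariate, 88 with that covariate and median-of-ratios scaling, 118 in the libraries with W-linked transcripts alone, and from 0 to 12 under the others that kept all libraries. Leaving out 1 library in turn ended 40 at least once, among them those of CD69L, EGR1, FN1, HIST1H2BO, HSPA2 from 1 to 6 days, ISCA2 from 1 to 3 days, PDE6B from 1 to 6 days and STS. One read is 0.0241 to 0.0361 CPM, which limits genes near the floor of 0.5 CPM.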

Other observations

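The clock set, the list permutations and the genes of the next paragraph were chosen after their values were seen.

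The lists of rod and cone genes moved both ways from 1 to 3 days, with 6 rises and 3 falls in 21 rod genes and 3 rises and 3 falls in 17 cone genes. Of these, 4 genes outside the rule for named genes were picked for a course lower at 3 days than before and after. NR2E3, a transcription factor of rod identity, stood at 2.10 ± 0.346, 0.773 ± 0.230 and 2.57 ± 0.626 CPM at 1, 3 and 6 days (SD, n = 7), with changes of -1.04 and +1.26 (limma adjusted p for the difference between the steps = 1.59e-06). GRK7, the cone opsin kinase, stood at 197 ± 10.6, 139 ± 14.7 and 203 ± 18.01 CPM. GUCA1C, a cyclase activator, stood at 203 ± 18.4, 139.5 ± 14.5 and 205 ± 19.3 CPM, and CNGA3, the cone channel, at 60.2 ± 7.64, 41.01 ± 9.58 and 62.3 ± 8.47 CPM. PER2, a clock repressor, had the same course, at 245 ± 20.52, 156 ± 24.1 and 239 ± 19.2 CPM (difference between the steps +1.28, limma adjusted p = 2.43e-06). PDE6B and RDH8 also had it. SLC24A1 (+0.77) and GNB1 (+0.44) rose from 1 to 3 days instead, as did ABCA4 (+0.53), and the opsin genes OPN1LW and OPN1MSW had the difference between the steps at -1.51 and -0.99 (limma adjusted p = 0.0224 and 0.0180). MTNR1A, a melatonin receptor, was lower at 6 days than at 1 day (-0.60), and TPH1, which starts melatonin synthesis, was highest at 3 days, at 14.8 ± 1.78 CPM against 10.9 ± 1.87 and 10.1 ± 0.759 CPM.

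The clock gene set, as activator-side minus repressor-side mean, stood at -0.44 ± 0.19 at 1 day, 0.45 ± 0.16 at 3 days and 0.00 ± 0.25 at 6 days (log2, SD, n = 7). From 1 to 6 days it differed by +0.44 (two-sided exact permutation p = 0.00408).

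Few other divisions of the libraries gave as many genes as the true one, which argues against chance for the counts of genes. With 100 divisions no share below 1 in 100 can be shown. Such divisions cannot separate age from anything else that differed between the groups. Of 100 divisions, 1 gave as many genes as the true one from 1 to 6 days (4103, highest other 38), 1 from 3 to 6 days (2813, highest other 1052), 1 at any time (4865, highest other 24) and 1 for the difference between the steps (1489, highest other 13), in each case the true division itself. From 1 to 3 days 2 did (1279, highest other 1513). That other division differs from the true one by the exchange of C23R and C42L alone, which leaves 2 libraries with W-linked transcripts in one part and 5 in the other. The division with 1052 exchanges C41R and C64L. For the number of gene lists chance could not be excluded: 15, 38 and 36 of 100 divisions gave as many lists as the true 5, 4 and 5 from 1 to 6, 1 to 3 and 3 to 6 days, with up to 9, 8 and 9 in another.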
